A study of Mus musculus with 54 samples.

How the data were processed

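Mouse 3T3-L1 cells, a fibroblast-like line that turns into fat cells in culture, were sampled at 18 times from 0 to 288 h in 3 arms. The arms were an untreated control undergoing normal differentiation, 0.5% DMSO (the vehicle) and 2 µM prieurianin (a limonoid, a plant triterpenoid). There was 1 array per arm and time, 54 arrays in all. Per the labels' protocols, total RNA was purified on columns, amplified to amino allyl RNA, coupled to Cy5 and hybridised to a single-colour mouse oligonucleotide array from Phalanx. The labels do not say whether separate cultures were used for each time, nor whether the treated arms received the differentiation stimulus at the same moment as the control. The scanner and any scaling are likewise not stated there.

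The deposited values are linear probe intensities, judged from the values themselves because no label states their unit. They ran from -83 to 65497, with 0.47% below 0; whether the authors subtracted a background is not given in the sources used here. Between 93 and 176 probes per array (median 121) lay within 50 units of that array's highest value and were treated as saturated. Median intensity per array ran from 88 to 313, so the deposited values had not been brought to a common distribution. The number of arrays limits the precision of every comparison.

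Values were quantile normalised between arrays, set to a floor of 0 and taken as log2(value + 16). All folds are therefore on the log2(value + 16) scale, which understates changes of dim genes. Of 29922 probes, 21020 carried 1 gene symbol in the platform annotation and none carried several. The other 8902 are unnamed here. Symbols were updated through a RefSeq gene table of assembly GRCm38.p6, used for names only: 17558 probes had a current symbol, 3410 were updated and 52 stayed as annotated. No coordinates are given because no build is stated for the array. Each of the 16637 genes was tested through its probe with the highest mean; 3566 genes had several probes. Genes with a mean log2 value above 6.07, the lower quartile of gene probes, were kept, which left 12792. No probe carried the symbol Cebpd here, and that gene was not analysed here.

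Comparisons between arms were made with limma 3.58.1 in R 4.3.3, with linear fits and moderated statistics. Time entered as a factor, so that arms were matched by time, and each arm had a separate effect in 3 windows: 0.25 to 3 h (5 times), 5 to 48 h (7 times) and 96 to 288 h (5 times). Times within a window stand in for replicates, and neighbouring times are not independent, so the p-values measure the spread of the arm difference between times. This spread was shared by all arms and windows, so late arrays also enter the error of the earlier windows. The 0 h arrays were left out of that fit, which had 28 residual degrees of freedom. Change over the course was tested in a second fit to all arrays, with a mean per arm and window and 0 h in the early window (45 residual degrees of freedom). It gave 96 to 288 h minus 0 to 3 h in each arm and the difference of these changes between arms. Adjusted p-values are Benjamini-Hochberg values from limma over all genes tested, with a threshold of 0.05. Errors written ± after a log2 value are standard errors from the fit, and SD is named where used. In comparisons between arms, rise and fall mean higher or lower than in the control arm at the same times, not a change over time.

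For the genes called in the untreated course, the change in each treated arm was divided by that in untreated cells and the median taken. List means per array were compared between matched times with exact two-sided sign-flip permutation tests. These tests take the times as independent, which neighbouring times are not, so their p-values may be too small. A total of 23 gene lists were tested with limma's camera at a preset correlation of 0.01. The lists were adipocyte effectors, adipogenic transcription factors, fatty acid synthesis, cholesterol synthesis, preadipocyte and anti-adipogenic genes, extracellular matrix, actin cytoskeleton and SRF (serum response factor) targets, cell cycle, immediate early genes, interferon response, inflammatory NF-kB targets, ER stress and amino acid response, heat shock, NRF2 targets, p53 targets, glycolysis and hypoxia, mitochondrial respiration and fatty acid oxidation. Marker lists of brown adipocytes, macrophages, skeletal muscle, bone and cartilage, and endothelial and epithelial cells covered other cell types. Camera p-values were adjusted over 92 tests. Camera with an estimated correlation and fry were alternatives, and with fry 26 of the 27 calls at the preset correlation held. Of the 27 calls at the preset correlation, 3 held with an estimated one: the actin list at 5 to 48 h and at 96 to 288 h, and the adipocyte list in the untreated course, the last not without every single time.

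Named genes followed a rule. For prieurianin against DMSO it took the 8 largest rises and the 8 largest falls among called genes with the same sign at every time of the window, and for other comparisons 5 each way. Where fewer than 3 genes passed, it took the 5 smallest p-values. Always given were Pparg, Cebpa, Cebpb, Fabp4, Adipoq, Plin1, Lpl, Cd36, Scd1, Fasn and Dlk1, and up to 4 members per list by size of change. A gene saturated on every array of the brighter group in a window has only a bound there, written as at least N-fold. Groups, windows, lists, the tests of arms and courses, most alternatives and this rule were fixed before the data were examined. The sign-flip tests of the actin list and of the adipocyte list against untreated cells, the test of late against middle differences, the fits without single arrays, the list tests without 192 h and some tests of explanations were added later.

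The procedure was tested on simulated data built from the means and spread of these arrays, with 12792 genes and known changes. The simulated noise was independent between times and between genes, and no simulated array stood apart. Neighbouring times of the real arrays are not independent, so the shares below describe an ideal case and may not hold for these data. For prieurianin against DMSO at 0.25 to 3 h it recovered 46.3%, 79.1% and 98.5% of genes changed by 0.5, 1 and 2 log2 units. At 5 to 48 h these shares were 61.2%, 98.5% and 100%, and at 96 to 288 h 44.8%, 92.5% and 100%. For the untreated course they were 25.4%, 76.1% and 98.5%. Unchanged genes made up 6.88%, 3.89% and 3.66% of the calls in the early, middle and late arm comparisons. Alternatives covered offsets of 1 and 64, median centring and the values as deposited in place of quantile scaling, a stricter filter and none, the mean of a gene's probes, array weights, a trended and robust variance, and no time block or a random one. They also covered other control groupings, a spline of time with 4 degrees of freedom, 0 h left out of the early window, and each time left out in turn. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.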

Results

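The time course followed 3T3-L1 preadipocytes, mouse cells that accumulate lipid and acquire fat cell markers in culture, for 288 h. The series set 2 µM prieurianin against 0.5% DMSO and against an untreated control undergoing normal differentiation, with 18 arrays per arm. Median intensity per array ran from 88 to 313, the highest being the untreated array at 1 h, and 93 to 176 probes per array were saturated. Correlations between pairs of arrays over all tested genes ran from 0.893 to 0.996. At 0 h, before any treatment time had passed, prieurianin and DMSO arrays differed by over 2-fold at 93 of 12792 genes (0.73%), and DMSO and untreated arrays at 292 (2.3%). The number of genes differing by over 2-fold between prieurianin and DMSO was 29 at 0.25 h, 508 at 0.5 h, 140 at 5 h, 998 at 15 h and 1710 at 288 h. With 1 array per arm and time, these per-time counts have no replicate check.

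**Figure D1:**
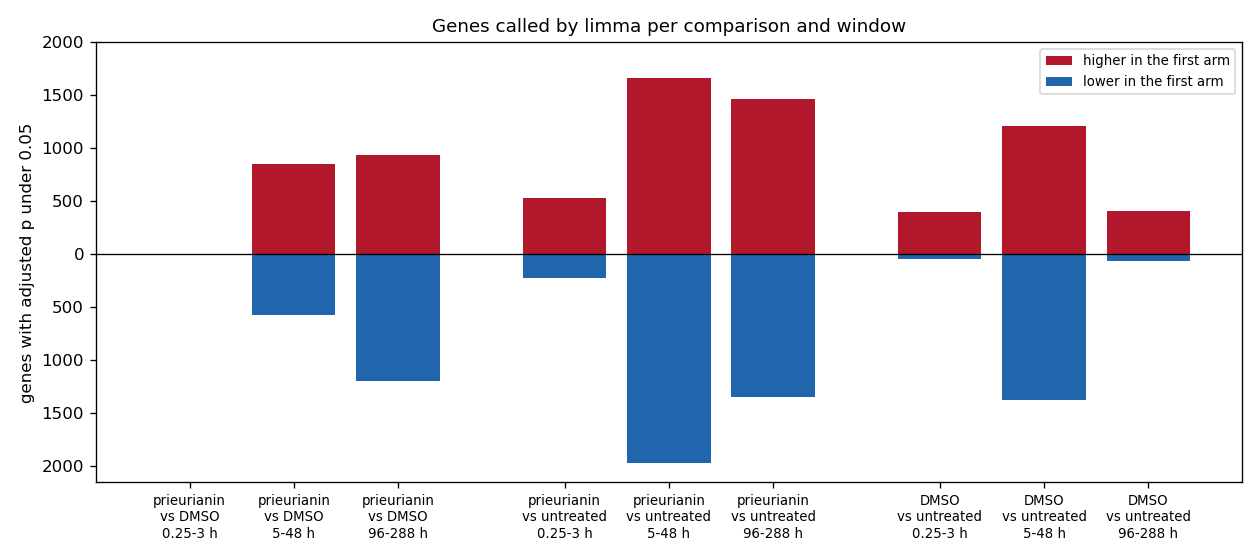
Genes with a limma adjusted p under 0.05 (vertical axis, number of genes; bars above 0 are genes higher in the first-named arm, bars below 0 genes lower) for each pair of arms in windows of 0.25 to 3 h, 5 to 48 h and 96 to 288 h. Prieurianin against DMSO gave 0, 1424 and 2133 genes in the 3 windows.

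The first comparison asked what the compound did beyond its vehicle. At 0.25 to 3 h no single gene separated the prieurianin and DMSO arms. The 5 genes with the smallest p were Amer1 (-0.45 ± 0.10, a regulator of Wnt signalling), Afdn (-0.47 ± 0.11, a junction protein that binds actin), Npat (-0.70 ± 0.17, an activator of histone genes), Vgll4 (-0.72 ± 0.18, a TEAD cofactor) and Trim35 (0.32 ± 0.08). Each had the same sign at 5 of 5 times and a limma adjusted p of 1. The fat cell genes were close to 0: Pparg -0.13 ± 0.21, Cebpa -0.04 ± 0.35, Cebpb -0.22 ± 0.11, Fabp4 0.02 ± 0.25, Lpl -0.08 ± 0.13, Scd1 -0.01 ± 0.33, Fasn 0.06 ± 0.37 and Dlk1 -0.07 ± 0.14, while Adipoq (0.03 ± 0.51), Plin1 (0.06 ± 0.52) and Cd36 (0.09 ± 0.26) were dim. By limma 0 genes were called and 300 (2.35%) had an unadjusted p under 0.05.

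Among the lists, actin cytoskeleton and SRF targets were higher as a group at 0.25 to 3 h, with a median of 0.21 over 17 genes of which 0 passed singly, and 0 when adjusted over the list alone. Camera gave an adjusted p of 0.00023, and the adjusted p was 0.35 with an estimated correlation. The mean difference of that list was 0.06 at 1 h, 0.34 at 2 h and 0.72 at 3 h, and the camera call was lost without 3 h (adjusted p = 0.068). Its members with the largest differences were Ankrd1 (0.60 ± 0.40), Ccn2 (0.57 ± 0.62), Vcl (0.41 ± 0.21) and Zyx (0.40 ± 0.18), none past the threshold. The other lists had 0 called members in this window, and camera called none of them (smallest adjusted p 0.25, fatty acid synthesis).

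At 5 to 48 h prieurianin cells had far more contractile and actin-linked transcripts than DMSO cells. Actg2, smooth muscle gamma-actin, rose 61-fold (5.93 ± 0.44, adjusted p = 1.5e-10), Myl9, the regulatory light chain of non-sarcomeric myosin, 29.4-fold (4.88 ± 0.40, 4.2e-10), and Acta1, skeletal alpha-actin, 8.16-fold (3.03 ± 0.26, 7.6e-10). Prnd, a prion-like membrane protein, rose 21-fold (4.39 ± 0.51, 2.1e-07), and Apol10b 9.05-fold (3.18 ± 0.27, 7.6e-10). Adm, a vasodilator peptide, rose 7.14-fold (2.84 ± 0.53, 0.00051), Inhba, the activin A subunit, 6.95-fold (2.80 ± 0.35, 1.2e-06), and Ccn2, a matricellular growth factor, 6.19-fold (2.63 ± 0.53, 0.0011). These 8 genes were higher at 7 of 7 times. Of the 17 actin and SRF genes, 16 rose and 0 fell, also when adjusted over the list alone, with a median of 1.57 and a camera adjusted p of 8.6e-29 (0.00091 with an estimated correlation); Ccn1 was another (2.51 ± 0.36, 1.3e-05). The list was higher with prieurianin at 17 of 17 times after 0 h, by 1.58 ± 1.05 (SD). The exact sign-flip permutation p was 1.5e-05, the smallest that test can give. Neighbouring times are not independent replicates of the treatment, so this p may be too small. Against untreated cells the list was higher at 15 of 17 times, by 1.57 ± 1.08 (SD, permutation p = 7.6e-05). The list mean went from 12.71 at 1 h to 10.86 at 48 h in DMSO cells, and from 12.78 to 12.74 in prieurianin cells.

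**Figure D2:**
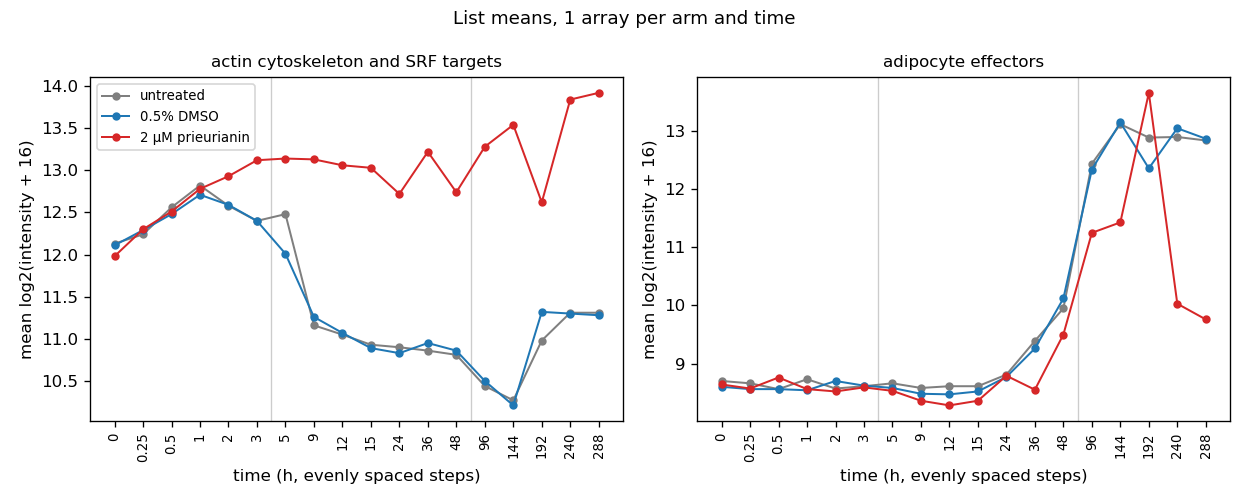
Mean log2(intensity + 16) of the actin and SRF list (left) and of the adipocyte effector list (right) against time in evenly spaced steps; each point is 1 array and vertical lines part the 3 windows. The prieurianin minus DMSO difference of the actin list was 0.72 at 3 h and 2.64 at 288 h, and that of the adipocyte list was 1.30 at 192 h and -3.11 at 288 h.

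The falls at 5 to 48 h were smaller. Retnla, a secreted resistin-like protein, was lowered 5.99-fold (-2.58 ± 0.46, adjusted p = 0.00028), Ltc4s, leukotriene C4 synthase, 2.01-fold (-1.01 ± 0.20, 0.00076), Edn2, endothelin 2, 1.97-fold (-0.98 ± 0.25, 0.0097) and Spon2, a matrix protein, 1.94-fold (-0.95 ± 0.21, 0.0034). Agt, angiotensinogen (-1.27 ± 0.41, 0.042), Cdc6 (-0.95 ± 0.25, 0.012) and Wdhd1 (-0.95 ± 0.26, 0.015), which act in DNA replication, and Il1rn, the interleukin 1 receptor antagonist (-0.93 ± 0.28, 0.025), fell at 7 of 7 times. The calls of these 4 depended on single times. Agt was lost without 9, 12, 15, 24, 36 or 48 h (adjusted p = 0.068, 0.082, 0.12, 0.059, 0.18 and 0.056), and Cdc6 without 9, 12 or 15 h (0.057, 0.077 and 0.076). Wdhd1 was lost without the same times (0.064, 0.08 and 0.1), and Il1rn without 12, 15 or 36 h (0.12, 0.14 and 0.078).

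Genes of glycolysis and hypoxia rose together at 5 to 48 h. Of 13 measured members 8 rose and 0 fell (9 adjusted over the list alone), among them Adm, Slc2a1, the basal glucose transporter (1.70 ± 0.27, adjusted p = 4.6e-05), Ndrg1 (1.45 ± 0.30, 0.0013) and Bnip3, a mitophagy receptor (1.10 ± 0.21, 0.00063). The list median was 0.58 with a camera adjusted p of 5.2e-07, and the adjusted p was 0.19 with an estimated correlation. Without 12 h or 15 h the count was 5. Immediate early genes had 6 rises and 1 fall among 16 (10 and 1 adjusted over the list alone), with Btg2, an antiproliferative factor, at 1.79 ± 0.24 (2.9e-06), Egr2 at 1.47 ± 0.24 (0.00011) and Atf3 at 1.25 ± 0.25 (0.0011). Their median was 0.42 (camera adjusted p = 9.3e-05; adjusted p = 0.095 with an estimated correlation), and without 9 h or 12 h 3 rose. Cell cycle genes were lower than in DMSO cells: 7 of 25 were lower and 0 higher (11 lower adjusted over the list alone). Their median was -0.40, with a camera adjusted p of 2.1e-07 (adjusted p = 0.46 with an estimated correlation). Without 9, 12 or 15 h 0 of them were called by limma, while camera still called the list (adjusted p = 2.4e-07, 8.4e-06 and 0.00013). The list mean went from 11.11 at 5 h to 12.15 at 15 h in DMSO cells, and from 11.02 to 10.92 in prieurianin cells. At 24 h it was 12.01 and 11.92. In untreated cells the list mean rose as in DMSO cells, from 11.05 at 5 h to 12.17 at 15 h and 12.14 at 24 h. The difference thus came from a rise in both controls that prieurianin cells did not show by 15 h. Top2a, a topoisomerase of dividing cells, was at -0.86 ± 0.28 (0.038) and was lost without 9, 12, 15 or 36 h (adjusted p = 0.096, 0.17, 0.17 and 0.053).

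ER stress and amino acid response genes had 4 rises and 0 falls of 16 at 5 to 48 h (5 adjusted over the list alone), including Ppp1r15a (0.80 ± 0.19, adjusted p = 0.0053) and Chac1 (0.74 ± 0.16, 0.0021). Their median of 0.10 gave a camera adjusted p of 0.042 (adjusted p = 0.34 with an estimated correlation), lost without 5, 9, 12 or 48 h (0.11, 0.079, 0.054 and 0.077). Of 5 skeletal muscle markers only Acta1 rose, also when adjusted over the list alone, with a median of 0.07 and a camera adjusted p of 0.042 (adjusted p = 0.26 with an estimated correlation), lost without 15, 36 or 48 h (0.11, 0.059 and 0.065).

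Few fat cell genes passed at 5 to 48 h. The mean of the adipocyte list lay between -0.19 and 0.01 from 5 to 24 h and was at -0.71 at 36 h and -0.62 at 48 h, each from 1 pair of arrays. Pparg, the master regulator of adipogenesis, was lower by 1.5-fold (-0.58 ± 0.18, adjusted p = 0.028, 6 of 7 times), a call lost without 9, 12, 15 or 36 h (adjusted p = 0.084, 0.13, 0.11 and 0.051). It was lost in 9 of 20 alternatives, among them time as a random block (0.07), no time block (0.28) and the fit of the prieurianin and DMSO arms alone (0.091). Not past the threshold were Cebpa (-0.22 ± 0.29), Cebpb (-0.02 ± 0.09), Fabp4 (-0.40 ± 0.21), Adipoq (-0.41 ± 0.43), Plin1 (0.14 ± 0.44), Lpl (-0.12 ± 0.11), Cd36 (-0.08 ± 0.22), Scd1 (0.12 ± 0.28), Fasn (-0.52 ± 0.31) and Dlk1 (-0.14 ± 0.12). Of 19 adipocyte effectors 0 passed, 0 also when adjusted over the list alone (median -0.20, camera adjusted p = 0.14). Without the 192 h arrays, which enter the shared error, 2 were lower and camera called the list (adjusted p = 0.029). That adjusted p was 0.57 with an estimated correlation. Of 12 adipogenic transcription factors Egr2 and Klf15 (1.02 ± 0.13, 2.7e-06) rose and Pparg fell, with 3 and 1 adjusted over the list alone (median 0.00, camera adjusted p = 0.44).

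The remaining lists were not called by camera at 5 to 48 h. Adjusted over the list alone, their counts equalled those over all genes unless stated. Fatty acid synthesis had 1 rise and 3 falls (median -0.01, adjusted p = 0.84), cholesterol synthesis 3 rises led by Dhcr7 (0.51 ± 0.14) and Sqle (0.43 ± 0.10) (0.09, 0.44), and preadipocyte genes 3 falls including Pdgfra (-0.73 ± 0.16; -0.04, 0.60; 1 rise also adjusted over the list alone). Extracellular matrix genes had 2 rises, one of them Thbs1 (1.29 ± 0.29), with a median of -0.03, a mean of 0.08 and an adjusted p of 0.72. Interferon genes had 0 calls (0.11, 0.47) and heat shock genes 0 (0.06, 0.77). NF-kB targets had 2 rises and 1 fall, the fall being Vcam1 at -0.90 ± 0.21 (-0.01, 0.96). NRF2 targets had 1 fall (0.11, 0.90), p53 targets 1 rise (-0.01, with a mean of 0.05, 0.96), mitochondrial respiration 2 falls (-0.06, 0.27) and fatty acid oxidation 1 fall (-0.14, 0.17). Among cell type markers, brown adipocyte (1 fall, Dio2 at -0.76; -0.37, 0.27), macrophage (1 fall; -0.09, 0.74), bone and cartilage (1 rise; 0.10, 0.53) and endothelial and epithelial lists (0 calls; 0.30, 0.44) were not called.

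In all, 1424 genes passed at 5 to 48 h, 847 higher and 577 lower, with 125 and 7 of them over 2-fold. With median centring in place of quantile scaling the split was 555 higher and 26 lower, and the calls of Spon2, Agt, Cdc6, Wdhd1, Il1rn, Top2a, Pparg, Pdgfra, Vcam1 and Dhcr7 were lost (adjusted p = 0.062, 0.13, 0.084, 0.066, 0.13, 0.25, 0.37, 0.17, 0.12 and 0.094). As deposited, Agt, Il1rn, Top2a, Pparg and Dhcr7 were lost (0.082, 0.052, 0.1, 0.1 and 0.19). Leaving out 12 h, 15 h or 9 h lowered the count to 655, 748 and 817.

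At 96 to 288 h, when untreated and DMSO cells carried the fat cell programme, prieurianin cells had lower fat cell transcripts and higher contractile ones. Adipoq, adiponectin, was lowered 6.6-fold (-2.72 ± 0.51, adjusted p = 0.00037, 5 of 5 times; saturated on 2 DMSO arrays), Cfd, adipsin, 10.9-fold (-3.45 ± 0.60, 0.00018), Gpd1, glycerol 3-phosphate dehydrogenase, 8.57-fold (-3.10 ± 0.63, 0.00092) and Cidec, a lipid droplet protein, 7.38-fold (-2.88 ± 0.59, 0.0011). Cfd, Gpd1 and Cidec were lower at 4 of 5 times, and Cfd was saturated on 2 DMSO arrays and 1 prieurianin array. The sizes depended on single times. Without 192, 240 and 288 h Cfd was at -4.37, -2.73 and -2.57, Gpd1 at -4.38, -2.47 and -2.12 and Cidec at -4.02, -2.21 and -2.09, while Adipoq was at -3.40 without 192 h and -2.06 without 240 h. The nuclear receptors Pparg (2.23-fold, -1.16 ± 0.21, 0.00023, 4 of 5 times) and Nr1h3 (3.12-fold, -1.64 ± 0.23, 8.4e-06, 5 of 5 times) fell, as did the fatty acid transporter Cd36 (2.63-fold, -1.40 ± 0.26, 0.00032, 4 of 5 times). Other large falls at 5 of 5 times were Ces1f, a carboxylesterase (7.49-fold, 7e-08), Apoc1, an apolipoprotein (5.53-fold, 4.7e-05), Iigp1, an interferon-inducible GTPase (4.21-fold, 3e-04), Vsir, an immune checkpoint protein (3.86-fold, 8.8e-05), Enpp2, autotaxin (3.75-fold, 7.5e-05), Slurp1 (3.71-fold, 9e-05) and Mc2r, the corticotropin receptor (3.53-fold, 2.9e-05). Iigp1 was at -1.45 without 192 h, beside -2.07 with all times, and Apoc1 at -1.88 without 240 h, beside -2.47.

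Among the other genes followed at 96 to 288 h, Cebpa (-1.20 ± 0.35, adjusted p = 0.016), Fabp4, a fatty acid carrier (-0.72 ± 0.25, 0.043), Plin1, the lipid droplet coat protein (-2.03 ± 0.52, 0.0069), and Scd1, a desaturase (-1.39 ± 0.33, 0.0039; saturated on 3 DMSO arrays and 1 prieurianin array), fell at 4 of 5 times. Each of these calls depended on single late times. Cebpa was lost without 144, 240 or 288 h (adjusted p = 0.056, 0.17 and 0.18) and was -1.85 without 192 h. Fabp4 was lost without 96, 144, 240 or 288 h (0.085, 0.082, 0.22 and 0.23). In this window Fabp4 was level with untreated cells, as given below, so its fall was against DMSO only. Plin1 was lost without 240 or 288 h (0.059 and 0.08) and was -2.64 without 192 h, and Scd1 without the same times (0.057, and 0.085 with a log2 difference of -0.86), being -2.11 without 192 h. Dlk1, a preadipocyte marker that inhibits differentiation, was lower at 3 of 5 times (-0.48 ± 0.14, 0.014), lost without 240 h (-0.30, 0.19) or 288 h (0.12). Cebpb (-0.06 ± 0.11) and Fasn (-0.26 ± 0.37) did not pass. Lpl was saturated on all 5 DMSO arrays and 1 prieurianin array, and no fold is given.

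**Figure D3:**
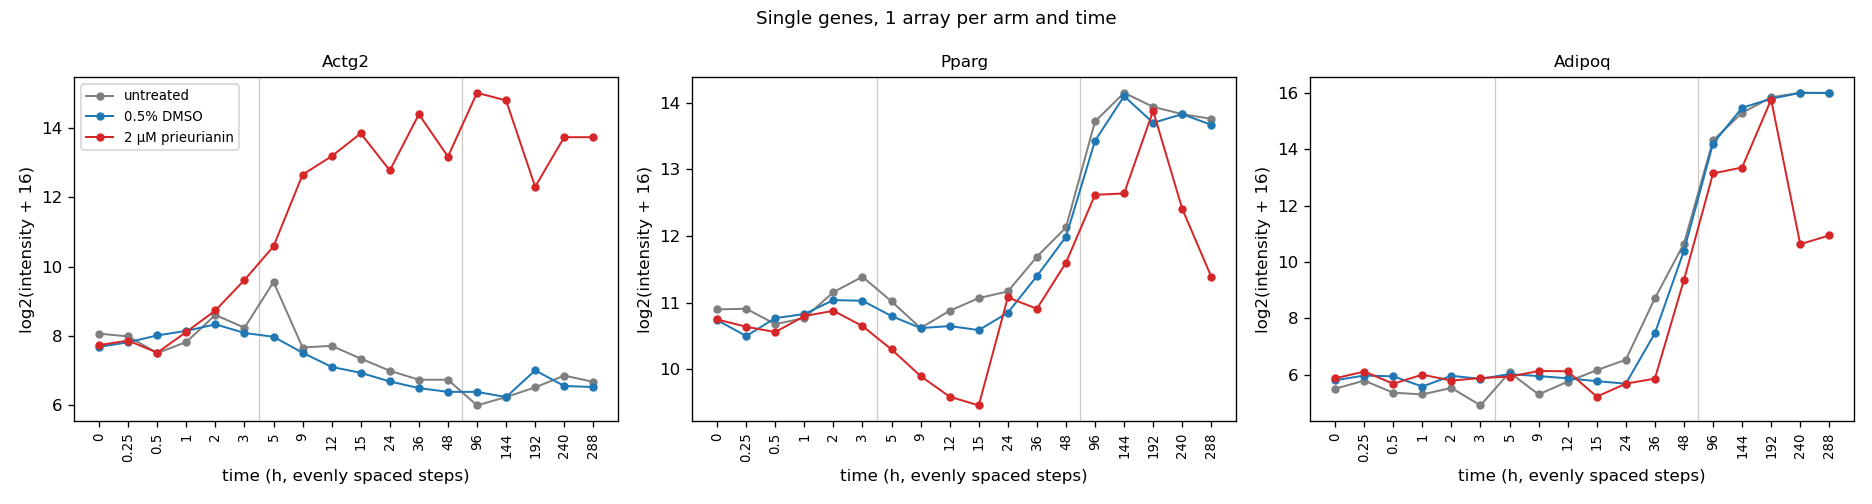
Log2(intensity + 16) of Actg2, Pparg and Adipoq against time in evenly spaced steps, 1 point per array, with vertical lines parting the 3 windows. At 192 h the prieurianin array had Adipoq at 15.76, beside 15.79 in DMSO, while at 240 and 288 h it stood at 10.63 and 10.94 beside 16 and 15.99.

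Of the 19 adipocyte effectors 14 fell and 0 rose at 96 to 288 h (17 adjusted over the list alone), with a median of -1.40 and a camera adjusted p of 4e-11. The adjusted p was 0.26 with an estimated correlation. Without 240 h or 288 h 8 of them fell, and without 192 h 18 (median -1.98, adjusted p = 0.01 with an estimated correlation). The mean of the list was lower with prieurianin at 4 of 5 late times, by 1.53 ± 1.80 (SD; mean difference -1.53), with an exact sign-flip permutation p of 0.19 where 0.062 is the smallest possible. Over 17 times it was -0.56 ± 1.13 (SD), lower at 12 (permutation p = 0.056 against DMSO), and -0.62 ± 1.04 against untreated cells, lower at 15 (permutation p = 0.016). The prieurianin array at 192 h stood apart: its adipocyte list mean was 13.66, beside 10.62 ± 0.84 (SD) on the other 4 late prieurianin arrays, and over all tested genes it correlated most closely with the untreated array at 144 h (r = 0.971 across genes, which are not independent). Without that time the late difference was -2.24 ± 1.00 (SD), lower at 4 of 4 times (exact permutation p = 0.12, the smallest possible).

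Contractile genes were higher than in DMSO cells at 96 to 288 h as well. Actg2 was 166-fold higher (7.38 ± 0.52, adjusted p = 2.1e-11), Myl9 71.7-fold (6.16 ± 0.47, 1.2e-10), Prnd 20.9-fold (4.38 ± 0.60, 6.7e-06), Acta1 14.4-fold (3.85 ± 0.30, 1.6e-10) and Tagln, transgelin, 10.7-fold (3.42 ± 0.23, 8.3e-12). Ankrd1, a mechanically induced ankyrin repeat protein, was 7.49-fold higher (2.90 ± 0.40, 7.4e-06), Acta2, smooth muscle alpha-actin, at least 6.45-fold (2.69 ± 0.39, 1.4e-05; saturated on 5 prieurianin arrays) and Glipr1 6.01-fold (2.59 ± 0.25, 1.3e-08). These 8 were higher at 5 of 5 times, and Ccn2 (26.5-fold, 4.73 ± 0.62, 4e-06) at 4 of 5. Without 192 h Ccn2 was at 6.01, Prnd at 5.47 and Ankrd1 at 3.53, and without 240 h Ccn2 was at 4.12. The 4 probes of Acta2 ran from 0.82 to 5.80. Of the 17 actin and SRF genes 16 were higher and 0 lower, also when adjusted over the list alone. Their median was 1.90 (camera adjusted p = 8.6e-29, and 0.00091 with an estimated correlation). In DMSO cells the list mean went from 12.11 at 0 h to 11.28 at 288 h, and in prieurianin cells from 11.98 to 13.92. Part of the difference was thus a fall in DMSO cells, where Ccn2 changed by -4.86 over the course. Tested against 5 to 48 h, the difference of the list was larger by a median of 0.57, with 2 of 17 members past the threshold (camera adjusted p = 0.0037; adjusted p = 0.31 with an estimated correlation). Skeletal muscle markers had 2 rises of 5, also adjusted over the list alone, Acta1 and Tnnt3 (1.32 ± 0.30, 0.0024; 0.85 without 192 h). Their median was 0.21 (camera adjusted p = 0.017; adjusted p = 0.19 with an estimated correlation), a call lost without 192 h (adjusted p = 0.16).

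Matrix genes rose in part at 96 to 288 h: 7 of 18 rose and 0 fell (8 adjusted over the list alone), led by Tnc, tenascin C (1.63 ± 0.19, adjusted p = 6.9e-07), Thbs1, thrombospondin (1.5 ± 0.34, 0.0025), Col1a1 (1.01 ± 0.18, 0.00029) and Postn, periostin (0.98 ± 0.17, 0.00023). The median was 0.32 (camera adjusted p = 0.0011; adjusted p = 0.34 with an estimated correlation). Without 192 h 10 rose (0.007 with an estimated correlation) and without 240 h 4 did. Of 25 cell cycle genes, 7 rose and 0 fell (10 adjusted over the list alone), with a median of 0.41 and a camera adjusted p of 1e-05 (adjusted p = 0.54 with an estimated correlation). Mki67, a proliferation marker, was at 0.97 ± 0.23 (0.004), but its 3 probes ran from -0.06 to 0.97 and the call was lost without 288 h (adjusted p = 0.066). By time, the list mean was at -0.28 at 96 h and -0.27 at 144 h, and at 0.78, 1.00 and 1.19 at 192, 240 and 288 h. The count of risen cell cycle genes was 14, 11, 4, 2 and 0 without 96, 144, 192, 240 and 288 h. The move from the middle to the late window was tested itself, with a median of 0.99 (camera adjusted p = 4.7e-15; adjusted p = 0.25 with an estimated correlation).

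Interferon response genes fell as a group at 96 to 288 h, with 7 of 17 lower and 0 higher (16 adjusted over the list alone), a median of -0.86 and a camera adjusted p of 9.6e-07 (adjusted p = 0.45 with an estimated correlation). This rested on 192 h: the list difference was -3.39 at that time, and without it 1 gene fell, the median was -0.29 and the adjusted p was 0.15. Much of that difference came from the DMSO array. Its list mean at 192 h was 11.78, beside 9.81 in untreated and 8.39 in prieurianin cells. Without 96 or 144 h 12 fell, and without 288 h 3. Ifit1 (-1.42 ± 0.37, 0.0075) was -0.83 without 192 h (adjusted p = 0.075), and Rsad2 (-1.56 ± 0.43, 0.011) was -0.90 (0.11), also lost without 288 h (0.088). Cholesterol synthesis genes had 6 rises and 0 falls of 14 (7 adjusted over the list alone; median 0.55, camera adjusted p = 0.00028; adjusted p = 0.45 with an estimated correlation), led among lasting calls by Sqle, squalene epoxidase (0.75 ± 0.12, 3.7e-05, 5 of 5 times). Without 192 h the median was 0.09 with 4 rises and 3 falls (adjusted p = 0.75). NRF2 targets had 3 falls of 11, also adjusted over the list alone, with Osgin1 at -1.22 ± 0.15 (7.2e-07) and Gsta4 at -0.65 ± 0.13 (0.00071). Their median was -0.31 (camera adjusted p = 0.03; adjusted p = 0.52 with an estimated correlation), lost without 192 h (adjusted p = 0.59).

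**Figure D4:**
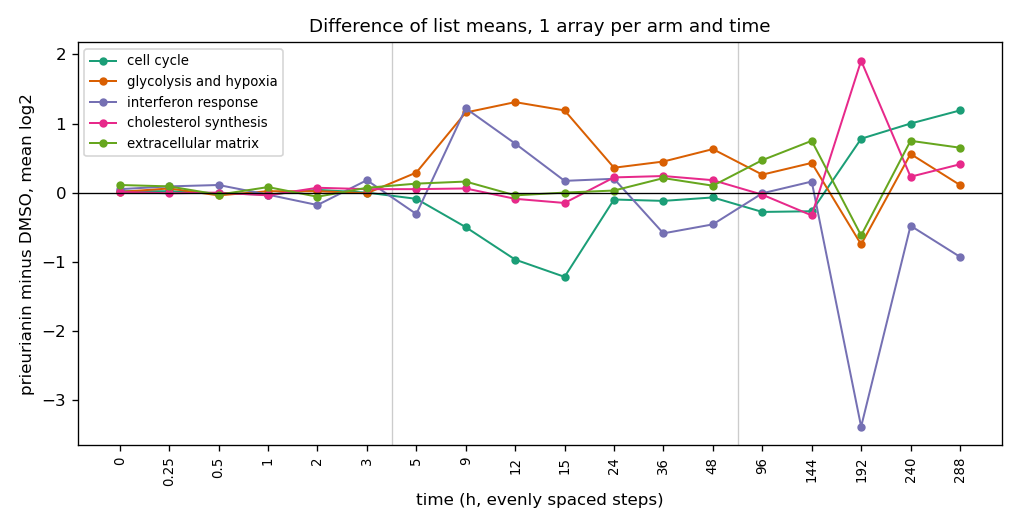
Prieurianin minus DMSO difference of the mean log2 value of 5 gene lists (vertical axis) against time in evenly spaced steps; each point is a pair of arrays and vertical lines part the 3 windows. At 15 h the cell cycle list was at -1.22 and the glycolysis list at 1.19, and at 192 h the cholesterol list was at 1.91 and the interferon list at -3.39.

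The other lists were not called at 96 to 288 h with all times. Adipogenic transcription factors had 2 rises and 3 falls of 12 (3 and 4 adjusted over the list alone; median -0.15, camera adjusted p = 0.44). Immediate early genes had 3 rises and 1 fall (6 and 1 adjusted over the list alone; 0.26, 0.099), with Dusp1 at 1.00 ± 0.21 and Egr1 at -0.99 ± 0.20. Preadipocyte genes had 3 rises and 3 falls (-0.13, 0.84), with Wnt5a, an anti-adipogenic ligand, at 0.71 ± 0.12 and Klf3 at -1.06 ± 0.15. Lists called without 192 h were fatty acid synthesis, mitochondrial respiration, fatty acid oxidation and NF-kB targets. Fatty acid synthesis had 2 rises and 5 falls (median 0.04, mean -0.19, 0.48), and without 192 h -0.28 with 1 rise and 6 falls (0.002; adjusted p = 0.078 with an estimated correlation). Mitochondrial respiration had 1 fall (-0.20, 0.074), and without 192 h -0.37 with 10 falls (4.7e-05; adjusted p = 0.015 with an estimated correlation). Fatty acid oxidation had 1 rise and 4 falls (-0.21, 0.15), and without 192 h -0.46 with 1 rise and 6 falls (0.0023; adjusted p = 0.02 with an estimated correlation), Cpt2, a mitochondrial carnitine transferase, being at -0.71 ± 0.16. NF-kB targets had 1 rise and 1 fall (-0.27, 0.56), and without 192 h 0.29 with 4 rises (0.029; adjusted p = 0.1 with an estimated correlation). ER stress genes had 3 rises (0.21, 0.2), heat shock genes 1 fall, Dnajb1 at -0.59 ± 0.12 (-0.11, 0.33), p53 targets 1 rise (0.00, 0.68), and glycolysis and hypoxia genes 1 rise and 1 fall (-0.04, 0.9; mean 0.12). Marker lists of brown adipocytes (0 calls; 0.47, 0.44), macrophages (0 calls; 0.03, 0.85), bone and cartilage (0 calls; -0.06, 0.84) and endothelial and epithelial cells (1 fall, Krt18 at -1.53 ± 0.31; -0.10, 0.39) were not called.

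At 96 to 288 h 2133 genes passed, 936 higher and 1197 lower, with 134 and 179 of them over 2-fold. On the values as deposited the split was 429 higher and 950 lower, and the call of Fabp4 was lost (adjusted p = 0.062). With median centring those of Fabp4, Dlk1, Mki67, Cpt2 and Dnajb1 were lost (0.078, 0.15, 0.075, 0.058 and 0.053). The count was 3302 without 192 h, 1011 without 240 h and 811 without 288 h. An F-test over the 3 windows called 2356 genes.

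The untreated course itself gave the background of differentiation. From 0 to 3 h to 96 to 288 h, Cfd rose 2010-fold (10.97 ± 0.76), Adipoq 1090-fold (10.09 ± 0.75), Cidec 703-fold, Sult1a1, a sulfotransferase, 164-fold and Gpd1 132-fold, all at 5 of 5 late times. The size depends on the offset added to these dim early values: over the alternatives Cfd ran from 9.47 to 12.23, Adipoq from 8.99 to 10.75, Cidec from 8.44 to 10.02 and Sult1a1 from 6.24 to 8.06. Cfd was saturated on 3 and Adipoq on 2 of the 5 late arrays. Pparg rose 7.53-fold, Cebpa 7.84-fold, Cd36 26-fold, Plin1 11.7-fold, Scd1 5.8-fold and Fabp4 5.29-fold. Scd1 was saturated on 3 late arrays and Lpl on 4, and no fold is given for Lpl. The largest falls were Il6 (35.2-fold), Ccn2 (30.1-fold), Mmp3, a matrix metalloprotease (21.2-fold), Nr4a1 (19.9-fold; -4.32, and -4.95 without 0 h) and Ccn1 (16.6-fold). Cebpb (-0.66) and Dlk1 (-0.44) also fell, and Fasn was at -0.04 ± 0.39 (limma adjusted p = 0.95). In all 4385 genes changed, 2169 higher and 2216 lower; as deposited, the split was 1091 and 2607.

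By list in the untreated course, 18 of 19 adipocyte effectors rose (median 3.23; camera adjusted p = 1.4e-21, and 0.044 with an estimated correlation). With an estimated correlation the adjusted p was 0.052, 0.059, 0.061, 0.05 and 0.053 without 0.25, 0.5, 3, 96 and 288 h. Of 12 adipogenic transcription factors 7 rose and 4 fell (median 0.82, adjusted p = 0.03; adjusted p = 0.34 with an estimated correlation). Mitochondrial respiration had 7 rises (8 adjusted over the list alone; median 0.33, 0.00042; adjusted p = 0.34 with an estimated correlation), and endothelial and epithelial markers 3 of 4 (4 adjusted over the list alone; 1.60, 0.01; adjusted p = 0.16 with an estimated correlation). Falls prevailed among cholesterol synthesis genes (12 of 14; -1.70, 2e-11; adjusted p = 0.19 with an estimated correlation) and cell cycle genes (20 of 25, 22 adjusted over the list alone; -1.49, 4.2e-10; adjusted p = 0.34 with an estimated correlation). They also prevailed among actin and SRF genes (12 of 17, with 1 rise adjusted over the list alone; -1.21, 1.8e-06; adjusted p = 0.26 with an estimated correlation) and immediate early genes (12 of 16; -2.14, 1.5e-05; adjusted p = 0.26 with an estimated correlation). NF-kB targets (10 of 16; -1.16, 0.00015) had an adjusted p = 0.34 with an estimated correlation, and interferon genes (11 of 17, 16 falls and 1 rise adjusted over the list alone; -1.46, 0.0015) an adjusted p = 0.62 with an estimated correlation. The interferon list did not stay low. Its untreated mean was 11.92 at 0 h, then 9.32, 8.97 and 9.81 at 96, 144 and 192 h, and 11.61 and 11.68 at 240 and 288 h. Preadipocyte genes (7 falls of 16; -0.46, 0.0077) had an adjusted p = 0.26 with an estimated correlation, and extracellular matrix genes (9 falls and 1 rise of 18; -0.68, 0.016) an adjusted p = 0.54 with an estimated correlation. The fatty acid oxidation list was just short of a call (5 rises and 1 fall, median 0.72, camera adjusted p = 0.061). It passed without 192 h (camera adjusted p = 0.049, and 0.41 with an estimated correlation). The remaining lists were not called.

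The same change was measured in both treated arms. In DMSO cells 4173 genes changed (2116 higher, 2057 lower; 1124 and 2107 as deposited), led by Cfd (11.23), Adipoq (9.64), Cidec (9.55), Gpd1 (7.11) and Sult1a1 (6.69), with falls of Ccn2 (-4.86), Il6 (-4.80), Mmp3 (-4.55), Fos (-4.14) and Ptgs2 (-4.02). Over the alternatives Cfd ran from 9.55 to 12.95 in DMSO cells and from 6.04 to 8.77 in prieurianin cells. In prieurianin cells 3884 changed (1963 higher, 1921 lower; 764 and 2336 as deposited), and the adipocyte genes still rose: Cfd by 7.48, Adipoq by 6.88, Cidec by 6.72, Pparg 3.67-fold, Cebpa 3.06-fold, Cd36 9.22-fold and Fabp4 3.12-fold. Actg2 (5.65) and Wfdc21 (4.37) were also among the largest rises, and Mmp3 (-4.33), Egr1 (-4.24), Cxcl5 (-4.21), Il6 (-4.16) and Cmpk2 (-4.14) the largest falls, all at 5 of 5 late times. Without 192 h the prieurianin course of Cfd was 6.54, of Adipoq 6.13, of Cidec 5.77, of Cxcl5 -2.99 and of Il6 -3.35. Without 240 and 288 h Cfd was at 8.12 and 8.28 and Cidec at 7.33 and 7.54, and without 288 h Il6 was at -4.94. Plin1 (1.32, adjusted p = 0.031) and Scd1 (0.94, 0.033) lost their calls without 192 h, at 0.66 (0.28) and 0.49 (0.24); Plin1 was also lost without 0, 0.25, 1, 2 or 3 h (0.052, 0.05, 0.065, 0.078 and 0.081), and Scd1 without 0, 0.25, 0.5, 1, 96 or 144 h (0.051, 0.054, 0.072, 0.056, 0.051 and 0.14).

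Over the 4385 genes that changed in untreated cells, the median gene reached 90.7% ± 13.4 (SD, n = 5 late arrays) of the untreated change in DMSO and 72.9% ± 21.7 (SD, n = 5) in prieurianin. By time the prieurianin share was 73.5%, 83.2%, 102%, 51.3% and 51.2% at 96, 144, 192, 240 and 288 h. It was 70.7% for rising genes and 75.3% for falling ones. The genes were chosen by their change in untreated cells, which is also the divisor. This choice alone can lower both shares without any effect of a treatment. The difference in share between the arms was not tested itself.

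The difference in course between prieurianin and DMSO, tested gene by gene, passed for 43 genes, 34 higher and 9 lower. The difference was positive for Actg2 (7.13 ± 0.63, adjusted p = 3.2e-11), Myl9 (5.96), Acta1 (3.57), Tagln (3.24) and Glipr1 (2.37), at 5 of 5 late times. Actg2 rose by 5.65 in prieurianin cells, less than its difference, so it fell in DMSO cells. The difference was negative for Ces1f (-2.93, 0.0076), Aox1, an aldehyde oxidase (-1.72, 0.019), Hsd11b1, which regenerates active glucocorticoid (-1.67, 0.005), Mfsd12 (-1.29, 0.038) and Cela1 (-1.01, 0.017). The call of Aox1 was lost without 0, 0.25, 1, 2, 240 or 288 h (adjusted p from 0.052 to 0.16), that of Mfsd12 without any time from 0 to 3 h, or without 144, 240 or 288 h (0.06 to 0.27), that of Cela1 without 0.25, 0.5, 1, 2, 240 or 288 h (0.053 to 0.13) and that of Ces1f without 240 h (0.055). The fat cell genes did not pass this test: Adipoq was at -2.76 ± 1.06 (0.35) and Pparg at -1.05 ± 0.42 (0.37). The fit behind this test did not match arms by time, so changes over time within each window entered its error. In the fit matched by time the late Adipoq difference from DMSO was of similar size (-2.72), and Adipoq and Pparg both passed there. Their failure to pass here thus does not show that their courses were alike in both arms. Without 192 h 497 genes passed the test of courses. Against untreated cells 76 genes passed, 53 higher and 23 lower (21 and 5 as deposited; 494 genes without 192 h), with Prnd at 4.19 beside Actg2 (7.24), Myl9 (6.36), Acta1 (3.83) and Tagln (3.31). Lower were Ces1f (-3.45), Ces3 (-3.14), Cmbl (-2.22), Ly6d (-1.89) and Hsd11b1 (-1.75). Ces3 was lost without 0, 0.25, 0.5, 1, 2, 240 or 288 h (adjusted p from 0.063 to 0.19), Cmbl without 0.25, 0.5, 1, 2, 3, 240 or 288 h (0.052 to 0.14) and Ly6d without 0, 0.5, 2, 3, 144 or 240 h (0.056 to 0.084). Without 192 h Prnd was at 5.19 and Ces3 at -3.84, and without 240 h Ces3 was at -2.39.

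The labels also set prieurianin against the untreated control. At 0.25 to 3 h 759 genes differed (532 higher, 227 lower). Yae1d1 rose 2.88-fold (1.52 ± 0.21, adjusted p = 0.00014), Mex3c, an RNA-binding ubiquitin ligase, 2.63-fold (0.00065) and Fbxl4 2.54-fold (0.00047), while Etv1, an ETS factor, fell by 0.97 (0.00035), Tapbp by 0.85, Rarg, a retinoic acid receptor, by 0.74 (0.00014) and Atp8b2 by 0.73, each at 5 of 5 times. Fabp4 was 2.24-fold higher (1.16 ± 0.25, 0.0037). Erap1 (1.54 ± 0.46, 0.04) was lost without any of the 5 times (adjusted p = 0.066, 0.25, 0.091, 0.061 and 0.14 without 0.25, 0.5, 1, 2 and 3 h), and Hmgb2 (1.33) and Psmd2 (-0.82) without 3 h (0.055 and 0.052). Cebpb (-0.41 ± 0.11, 0.015) was lost without 0.25 h or 3 h (0.086 and 0.12). The split was 189 and 13 with median centring and 165 and 143 as deposited, and the count was 205 without 3 h, 380 without 0.25 h and 465 without 1 h.

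At 5 to 48 h prieurianin and untreated cells differed at 3642 genes, 1664 higher and 1978 lower (962 and 2327 as deposited). Actg2 (42.4-fold), Myl9 (23-fold), Prnd (15.8-fold), Tmsb4x, thymosin beta 4, which binds actin monomers (10.9-fold), and Acta1 (7.22-fold) rose; without 5 h Actg2 was at 6.14, beside 5.41 with all times, and Myl9 at 5.15, beside 4.52. Retnla (6.69-fold), Cldn15 (3.05-fold), Wnt4, a Wnt ligand (2.74-fold), and Edn2 (2.57-fold) fell at 7 of 7 times. Pparg was 1.77-fold lower (-0.82 ± 0.18, adjusted p = 0.00061) and Fabp4 2.18-fold higher (0.00013). Cidec (-1.52 ± 0.50, 0.022) was lost without 15 h or 36 h (adjusted p = 0.07 and 0.1), Lpl (-0.34, 0.016) without the same times (0.086, and 0.13 with a difference of -0.21) and reversed to 0.19 (0.22) with the mean of its probes, and Cebpb (-0.29, 0.014) without 24 h (0.052). At 96 to 288 h 2811 genes differed, 1462 higher and 1349 lower (594 and 2217 as deposited; 1750 without 240 h). Actg2 (176-fold), Myl9 (85.5-fold), Prnd (21.9-fold), Acta1 (16-fold) and Tagln (9.34-fold) led the rises. Ces1f (9.61-fold), Sult1a1 (9.45-fold), Ces3 (8.21-fold) and Apod, an apolipoprotein (7.4-fold), led the falls at 5 of 5 times. Pparg (-1.29), Cebpa (-1.64), Adipoq (-2.72), Plin1 (-2.17), Cd36 (-1.12) and Scd1 (-1.74) fell, while Fabp4 (0.00 ± 0.25) and Fasn (-0.34 ± 0.37) did not pass. Tmem258 had the largest fall (-6.70 ± 2.23, 0.028), lost without 96, 192, 240 or 288 h (adjusted p = 0.075, 0.07, 0.094 and 0.083) and at -8.36 without 144 h. Without 192 h Prnd was at 5.46, beside 4.45 with all times, Adipoq at -3.39, Plin1 at -2.94, Ces3 at -3.73, beside -3.04, and Sult1a1 at -3.83, beside -3.24. Without 240 h Adipoq was at -2.06, Ces3 at -2.29, Sult1a1 at -2.41 and Apod at -2.22, beside -2.89. Sult1a1 was at -3.84 without 96 h and -2.43 without 288 h, and Apod at -3.60 without 144 h.

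The vehicle alone was set against untreated cells as the background of the treatment. At 5 to 48 h 2596 genes differed, 1212 higher and 1384 lower. Tmsb4x rose 4.98-fold, Ifit1, an interferon-induced gene, 3.98-fold, Acap2 3.69-fold, Hmgb2, a chromatin protein, 3.68-fold and Cwc15, a splicing factor, 3.52-fold. Psmd2 and Adrm1, of the proteasome, fell by 0.96 and 0.86, Etv1 by 0.91, Kcnh3 by 0.88 and Atp8b2 by 0.87, all at 7 of 7 times. Fabp4 was 2.88-fold higher (1.53 ± 0.21, adjusted p = 2.8e-06), while Pparg (-0.24 ± 0.18, 0.36) and Adipoq (-0.29 ± 0.43, 0.68) did not pass. Cebpb (-0.27, 0.03) was lost without 5, 9, 15, 24 or 36 h (adjusted p = 0.059, 0.055, 0.074, 0.062 and 0.11). The split was 539 and 2227 with median centring, which moved the median of all genes to -0.18, and 748 and 1331 as deposited.

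At 0.25 to 3 h DMSO and untreated cells differed at 453 genes, 401 higher and 52 lower (86 and 25 as deposited). Cwc15 (2.9-fold, adjusted p = 0.002) and Yae1d1 (2.82-fold, 0.00035) were higher at 5 of 5 times. Sgce (1.51), Hmgb2 (1.37), Smad7 (1.27) and Fabp4 (1.14) were higher, and Cnfn (-0.92), Ramp3 (-0.82), Psmd2 (-0.73), Tapbp (-0.70) and Chd4 (-0.69) lower, but each call was lost without some time. Without 3 h these were Sgce, Hmgb2, Smad7, Fabp4, Ramp3, Psmd2, Tapbp and Chd4 (adjusted p = 0.071, 0.076, 0.061, 0.08, 0.11, 0.16, 0.057 and 0.17). Without 0.25 h they were Sgce, Hmgb2, Smad7, Fabp4, Cnfn, Psmd2 and Chd4 (0.13, 0.084, 0.05, 0.088, 0.06, 0.16 and 0.14), without 1 h Sgce and Ramp3 (0.05 and 0.2) and without 2 h Ramp3 and Psmd2 (0.053 and 0.059). With the mean of its probes Chd4 was at -0.11 (0.73). The count was 83 without 0.25 h, 86 without 3 h, 204 without 1 h, 253 without 2 h, 672 without 0.5 h and 235 without the untreated 1 h array alone. At 96 to 288 h 467 genes differed, 402 higher and 65 lower (32 and 0 with median centring, 17 and 0 as deposited). Sh3bp4 (2.27-fold, 0.00035), Phyh, a peroxisomal hydroxylase (2.15-fold, 0.0016), Edem1, of ER protein quality control (2.12-fold, 0.00099), and Slbp, the histone mRNA binding protein (2.11-fold, 0.0024), were higher at 5 of 5 times. Zfp503 (1.15), Get3 (-0.76), Med13l (-0.70), Pef1 (-0.70) and Msln (-0.68) lost their calls without 144 h (adjusted p = 0.17, 0.16, 0.16, 0.15 and 0.13), without 192 h (0.056, 0.052, 0.12, 0.074 and 0.098) and without 240 h (0.16, 0.086, 0.11, 0.091 and 0.24). Without 96 h Zfp503, Chst12 (-0.72), Pef1 and Msln were lost (0.15, 0.057, 0.13 and 0.11), and without 288 h Msln (0.051). All 6 were also lost with either other scaling. Pparg (-0.13), Cebpa (-0.44), Adipoq (0.00), Cd36 (0.28) and Fabp4 (0.72, 0.11) did not pass. The count was 108 without 240 h, 125 without 144 h, 230 without 96 h and 280 without 192 h.

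On the values as deposited the median of all genes moved to -0.12 and -0.17 in prieurianin against untreated cells (early and late), to -0.13 and -0.14 in DMSO against untreated cells, and to -0.16, -0.15 and -0.15 in the untreated, DMSO and prieurianin courses, while after quantile scaling these medians lay between -0.02 and 0.03.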

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

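The tests of exchanged labels, of mixed RNA, of skeletal muscle cells and of cross-hybridisation were chosen only after the results were seen. So were the fits without single arrays, the list tests without 192 h and the test of late against middle differences. The other tests were written down before their results were seen.

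Within windows, 71 groups of array pairs or arrays were searched for a single value far from the rest, and 13 had one where chance alone gives about 1 in 20, or 3.5. At 192 h the prieurianin minus DMSO difference lay far from the other 4 late times for adipogenic transcription factors (0.40, others -0.45 to -0.24), fatty acid synthesis (1.26, others -0.68 to -0.38) and extracellular matrix (-0.62, others 0.47 to 0.75). It did so too for NF-kB targets (-3.05, others 0.22 to 0.71), mitochondrial respiration (0.64, others -0.56 to -0.28), fatty acid oxidation (0.59, others -0.46 to -0.29) and brown adipocyte markers (2.46, others -0.16 to 0.07). Elsewhere, the actin and SRF list stood at 1.13 at 5 h (others 1.87 to 2.26) and ER stress genes at 0.14 at 3 h (others -0.08 to -0.02). Heat shock genes stood at -0.03 at 0.5 h (others 0.05 to 0.07), p53 targets at 0.06 at 0.25 h (others -0.04 to -0.03) and fatty acid oxidation at -0.04 at 2 h (others 0.02 to 0.03). The DMSO share of the untreated change was 114% at 144 h, beside 81.3% to 88.4% at the other late times.

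The prieurianin array at 192 h had an adipocyte list mean of 13.66, above all 10 late control arrays (12.34 to 13.15), and an interferon list mean of 8.39, below all of them (8.90 to 11.78). An exchange of labels with the DMSO array of that time is argued against, since its actin list mean of 12.62 lay 1.30 above the highest of 10 late control arrays, and the DMSO array showed no high actin list (11.32, next control 11.31). Prieurianin RNA mixed with control RNA is argued against by the cholesterol list, 0.92 above the highest of the 14 other late arrays, where a mixture has to lie between its parts. The actin list mean did lie between the controls and the other late prieurianin arrays (lowest 13.28), as in a mixture. Scaling is argued against because the adipocyte list departed by 3.16 as deposited, 3.04 after quantile scaling and 3.23 after median centring. A different culture or a single wrong label may account for the array and was not tested, and no biological explanation was tested.

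DMSO and untreated arrays differed at 453 genes within 3 h. An offset of the untreated arrays already present at 0 h is argued against as the whole cause by the prieurianin array of that time, since 226 of the 453 genes (49.9%) had the same sign in prieurianin minus untreated at 0 h, beside 61.6% over all genes, which leaves a part of it open. In DMSO minus untreated 315 had (69.5%), so an offset of the DMSO arrays may contribute. Whether the bright untreated array at 1 h made the difference cannot be told: the count was 204 without 1 h, but also 83, 253 and 86 without 0.25, 2 and 3 h, and 672 without 0.5 h. A biological effect of the vehicle stays open and was not tested.

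The late difference of the actin and SRF list, part of which was a fall in DMSO cells, was set against 3 technical explanations. Skeletal muscle cells in the cultures are argued against by the median of 0.16 over 9 skeletal muscle markers other than Acta1, although Tnnt3 was at 1.32. Of these markers, Myod1, Myf5, Ckm, Myh3 and Mb were too dim to pass the filter. Among those that passed it, Myog was at 0.13, Des at -0.21 and Tnnc1 at 0.21. Smooth muscle cells are not addressed by these markers, and several of the higher genes are smooth muscle genes. Scaling is argued against by a list median of 1.87 on the values as deposited, and cross-hybridisation among actin transcripts by a median of 1.75 over the 14 members that are not actins, 13 of them higher. A response of the treated cells is a hypothesis that stays open, found and tested on the same arrays.

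Between 5 to 48 h and 96 to 288 h the prieurianin minus DMSO difference itself changed for 862 genes by limma. By list, with camera adjusted p in brackets, the median moved by -1.29 for adipocyte effectors (5.2e-07), -0.44 for adipogenic transcription factors (0.049), 0.33 for cholesterol synthesis (0.0073) and 0.22 for extracellular matrix (0.0067). It moved by 0.57 for the actin list (0.0037), 0.99 for cell cycle (4.7e-15), -1.06 for interferon response (2.2e-07), -0.45 for NRF2 targets (0.013) and -0.73 for glycolysis and hypoxia (0.00011). None of these held with an estimated correlation (adjusted p from 0.25 to 0.42), and without 192 h the calls of cholesterol synthesis (0.97) and NRF2 targets (0.28) were lost. The change over the course differed between prieurianin and DMSO for 43 genes and between prieurianin and untreated cells for 76. Of 4609 tested probes unnamed here, 336 differed between prieurianin and DMSO late (124 higher, 212 lower), 7.29% beside 16.7% of named genes.

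Chance was judged from 100 regroupings of the arrays per comparison, the real one included. For the count over all windows and for the differences in course these exchanged arms within times. For single windows and courses they were splits that do not keep arms or times matched. Each arm is 1 series of single arrays, so no regrouping tells the treatment from another difference between the arrays of the arms. Such a difference was seen: at 5 to 48 h, 143 to 275 probes were below 0 on untreated arrays. On DMSO arrays 76 to 127 were, and on prieurianin arrays 81 to 136. At 96 to 288 h the numbers were 173 to 252 on untreated, 81 to 139 on DMSO and 87 to 141 on prieurianin arrays. Calls over 2-fold in DMSO against untreated cells were all higher (43, 165 and 20 in the 3 windows, with 0 lower). In prieurianin against untreated cells 68, 264 and 215 were higher and 0, 33 and 168 lower. Chance can be excluded (1 of 100 as large) for prieurianin against DMSO over all windows (2356 genes, highest other 1688). It can be excluded by the unmatched splits and by exchanges within times (1 of 64 as large, the real one) in the windows of 7 times. There prieurianin against DMSO called 1424 (highest other split 1273, highest other exchange 796), prieurianin against untreated cells 3642 (1630, 2142) and DMSO against untreated cells 2596 (1251, 1557). By the splits it can be excluded for the untreated, DMSO and prieurianin courses (4385, 3375; 4173, 2956; 3884, 2462), whose early and late arrays have no matched times. In the windows of 5 times the exchanges that keep arms matched number 16, too few for a share under 0.05. There prieurianin against DMSO late called 2133, and 3001 with the 192 h arrays alone exchanged, the highest; 2 of 16 exchanges and 4 of 100 splits were as large, the real one included. Prieurianin against untreated cells called 759 early (highest other exchange 78, split 599) and 2811 late (2679, 2780). DMSO against untreated cells called 453 early (347, 330) and 467 late (182, 716), where 6 of 100 splits were as large. For prieurianin against DMSO at 0.25 to 3 h the real count was 0, which all 100 splits reach by construction (highest other 1), so they say nothing there. Chance cannot be excluded for the differences in course (43; 7 as large, highest 304, and 76; 14 as large, highest 641). For these differences some exchanges called several times the real count, which points to a structure of the samples. The exchange that gave 304 took every late time but 192 h, and 2 of the 6 other exchanges as large, that one included, and 5 of 13 against untreated cells set 192 h apart from most late times. The structure was not identified further.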

How the results depend on the processing

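The fits without the prieurianin or DMSO array at 192 h, or the untreated array at 1 h, were chosen only after the results were seen; the other alternatives were planned. Offsets of 1 and 64, no filter, the mean of a gene's probes, a trended and robust variance, time as a random block and 0 h left out kept every count within 1.5 times, and the spline did so for the count over all windows. Dim and saturated probes limit what folds can show. For every change given here the cause was not tested, except that fewer times or arrays lower power.

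With median centring, prieurianin against DMSO gave 581 and 810 genes (middle, late) and 826 over all windows, prieurianin against untreated cells 202, 2297 and 1327, DMSO against untreated cells 155 early and 32 late, and the differences in course 28 and 38. As deposited, the first gave 647 and 1379 and 1158 over all windows, prieurianin against untreated cells 308 early, DMSO against untreated cells 111 early and 17 late, and the differences in course 20 and 26. With array weights, whose estimation stopped short of its convergence tolerance, counts were 3249 for prieurianin against DMSO late, 3558 over all windows, 2772 for prieurianin against untreated cells early, 2243 and 1331 for DMSO against untreated cells early and late, and 1148 and 1002 for the differences in course. The mean of DMSO and untreated as control gave 2655 in the middle window and 4228 over all windows, and only the prieurianin and DMSO arms 1230. Without the prieurianin array at 192 h counts were 3410 late, 3731 over all windows, and 521 and 628 for the differences in course; the adipocyte difference over the course was -0.67 (exact permutation p = 0.0038), and -0.57 (permutation p = 0.041) with the stricter filter. Without the untreated 1 h array DMSO against untreated cells early gave 235. With an estimated correlation 3 list tests passed, and with fry 34. Among named genes, calls were lost for 57 of 272 with median centring, 44 of 272 as deposited, 92 of 196 with no time block, 30 of 196 with a random one, 35 of 121 with only 2 arms, 14 of 273 with array weights, 9 of 273 with no filter and 6 of 272 with the mean of probes. Signs reversed for Lpl in prieurianin against untreated cells middle (0.19 with the mean of its probes) and for Nr2f2 in prieurianin against DMSO middle (0.07 against the mean of both controls).

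Times matched the arms as a block. Without the block, prieurianin against DMSO gave 411 and 657 genes (575 over all windows), prieurianin against untreated cells 280, 1962 and 1227, and DMSO against untreated cells 188, 1366 and 125.

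Leaving out each time in turn gave 655 to 1491 genes for prieurianin against DMSO middle, 811 to 3302 late and 1456 to 3673 over all windows. Prieurianin against untreated cells gave 205 to 713, 2604 to 3532 and 1750 to 3647, and DMSO against untreated cells 83 to 672, 1774 to 2691 and 108 to 648. The differences in course gave 26 to 497 and 41 to 494, the courses 3743 to 4474 (untreated), 3491 to 4190 (DMSO) and 3368 to 3978 (prieurianin), and the adipocyte difference -0.67 to -0.40.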

Other observations

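The test of which list moved first was chosen only after the result was seen; the test of opposition to the differentiation change, with and without 192 h, was written down before its result was seen.

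Middle and late differences from DMSO share no arrays, and their calls overlapped. Of 847 genes higher at 5 to 48 h and 936 higher at 96 to 288 h, 288 were in both sets, beside 62 for independent sets, and 111 were lower in both, beside 54. Opposite calls were fewer than for independent sets, 22 higher then lower (79.3) and 14 lower then higher (42.2). Both windows share 1 error per gene, so a gene with little spread is more readily called in both. The counts for independent sets are thus no strict baseline, but the sign of a difference does not depend on that error. Actg2 was 0.40 above DMSO at 2 h, 1.53 at 3 h, 2.60 at 5 h, 5.15 at 9 h and 8.64 at 96 h, each from 1 pair of arrays. The interferon list was 1.22 above DMSO at 9 h and 0.71 at 12 h.

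A hypothesis is that the late changes with prieurianin may oppose those of normal differentiation. Of 1118 genes called in both prieurianin against DMSO late and the untreated course, which share no arrays, 903 (80.8%) had opposite signs, with 496 of 558 rising genes and 407 of 560 falling genes. Without 192 h it was 1391 of 1628 (85.4%). Both values fit the hypothesis, but a delay of differentiation and a loss of its later part were not told apart.

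Prieurianin has been described as stabilising actin filaments in plant cells, and a hypothesis is that the actin change may come first. The actin and SRF list passed the bound set by its 0 to 1 h differences (0.13) from 2 h on. The adipocyte list did so from 240 h on, or from 36 h without 192 h. The order cannot be told, because at 0.25 to 3 h the adipocyte list had not yet risen in DMSO cells (mean 8.60), so a weaker rise could not show. With 3 of its 19 members below the filter level at those times, the list did have room to fall below its starting level.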
